A study of Mus musculus with 4 samples.

How the data were processed

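Droplet-based single-cell RNA sequencing with 3' counting was carried out on inner ear organoids of 4 groups, WT and KO at day 25 and day 35, with 1 library per group. Per the labels, organoids were dissociated with TrypLE, passed through a 40 µm strainer, washed in 2% BSA and loaded for a target of 10000 cells per library. Each sample was assigned to its genotype and day from its label.

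The deposited matrices hold UMI counts per gene and cell barcode, made by the authors, as whole numbers without normalization. The submitters' processing notes name Cell Ranger 2.1.0, bcl2fastq, Seurat 2.3.1 and R 3.5.1 and the builds mm10 and GRCm38, without saying which step made the matrices. The counting settings, such as strand and the treatment of reads that match several genes, are not given in the sources used here. Gene identifiers were matched to a GRCm38 gene annotation for positions, and 27645 of 27998 were found.

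Barcodes with at least 500 detected genes and at most 10% mitochondrially encoded UMIs were kept, which left 9768 of 9963 (98.0%), 11190 of 11307 (99.0%), 8166 of 9250 (88.3%) and 6729 of 7077 (95.1%) in WT and KO at day 25 and WT and KO at day 35. The mitochondrial limit removed 195, 117, 1081 and 348 barcodes. Doublets were scored against simulated doublets at an expected 0.8% per 1000 barcodes. The score threshold called 0, 0, 0 and 3 barcodes, under 0.5% of more than 5000 cells, so the caller had not worked and no cell was removed as a doublet. Removing the highest scores at the expected rate (794, 1023, 684 and 401 barcodes) was tried instead as an alternative.

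The kept cells of all 4 libraries were clustered together without batch integration, on log-transformed scaled counts of 2000 variable genes, 30 principal components, 20 nearest neighbours and the Leiden method at resolution 1.0 with a fixed seed. Tmprss3, mitochondrially encoded, ribosomal protein, imprinted, Y-linked and Xist genes were left out of the variable genes. Members of the gene lists described below were left out as well, unless they were cell type markers. The 27 clusters were ranked for leading genes by fold over the other cells after adding 10 CPM. A cluster was named after 1 of 24 marker sets when at least 3 of its markers were among the 50 leading genes and at least 2 among the top 20, provided no other set had more markers among the top 10. These thresholds were set after the data were examined, while the markers were fixed before. They gave 12 named classes and left 11 clusters unnamed. The unnamed clusters 2, 3 and 4 alone held 16.0%, 18.3% and 16.9% of WT cells at day 35, and 18.1%, 11.8% and 11.7% of KO cells. At day 25 the unnamed cluster 0 alone held 16.4% of WT and 24.2% of KO cells. The shares of named classes therefore leave out much of each library on both days.

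UMIs were summed per class and library and expressed as CPM of all UMIs of that class and library. Shares have exact Clopper-Pearson intervals, levels exact Poisson intervals, and ratios intervals from the conditional binomial distribution, all at the 95% level. A count of 0 was set to a floor of 3 counts over the class in a ratio, and the exact bound is given beside it. Cells are not replicates, so no test was made. The intervals were tried on Poisson counts drawn from the class profiles at the real depths. This is the counting model that the intervals assume, so the trial shows only what counting error allows. Uneven cells and doublets were not simulated. In hair cell-like cells 76% of 100 genes with a simulated 2-fold difference had an interval without 0 at day 25 (730 genes) and 83% at day 35 (1054 genes), and in other otic epithelial-like cells 95% on each day (7777 and 10398 genes). All of the 4-fold differences were recovered in each comparison.

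Before the data were examined, the design, the markers, 23 gene lists and the genes to be named were fixed. In hair cell-like cells, genes with at least 50 UMIs over the 2 libraries compared were named as follows, leaving out Tmprss3, mitochondrially encoded and ribosomal protein genes. For both days, up to 10 higher and 10 lower genes had a log2 ratio of at least 1 in size in the same direction on each day, ranked by the interval bound nearest 0. For each day alone, 5 higher and 5 lower genes were ranked by that bound. For day 35 over day 25, 10 higher and 10 lower genes in WT needed the same direction and at least 1 in size in KO. A gene was not named where its interval included 0 in a comparison that its rule used. In other classes 5 higher and 5 lower genes were named under the rule for both days, and list members and markers could be named besides. Some results that these rules would name are not reported here. A list's median log2 ratio, over members with at least 20 UMIs, was placed as a percentile among 10000 random lists of the same size matched on expression in 20 bins, as a description of these libraries. Clusters with enough cells in both genotypes of a day were also compared pair by pair.

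Alternatives covered the cell filter, resolution, variable genes, clustering of each library alone, a per-cell rule after thinning to 1500 UMIs, scaling and UMI minimums. Work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. For TMM scaling of the counts, R 4.3.3 with edgeR 4.0.16 was used.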

Results

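Single-cell transcriptomes were collected from inner ear organoids, three-dimensional cultures in which mouse embryonic stem cells form otic epithelium with hair cells, the sensory receptors of hearing and balance. The wild-type (WT) organoids came from the R1/E line, and the knockout (KO) organoids from an R1/E line in which Tmprss3 was disrupted and a GFP reporter inserted. Tmprss3 encodes a type II transmembrane serine protease whose loss causes hearing loss. Organoids were taken at day 25 and day 35, which gave 4 libraries with 1 library per genotype and day. The libraries held 9963 barcodes and 75064434 UMIs (WT, day 25), 11307 and 85808118 (KO, day 25), 9250 and 35749960 (WT, day 35), and 7077 and 40518939 (KO, day 35). Median UMIs per barcode were 6190 and 6378 for WT and KO at day 25, and 3114 and 4448 at day 35. With no replicate of any group, no difference below has a test. Intervals of shares, levels and ratios are exact 95% intervals that cover counting error alone, not the variation between cultures or between cell lines. Intervals of medians are order-statistic 95% intervals over members, such as genes of a list or pairs of clusters. They describe the spread among those members and do not cover that variation either.

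The targeted gene was examined first. Tmprss3 (ENSMUSG00000024034; GRCm38 chromosome 17, 31179265 to 31198977, minus strand) gave 18 UMIs in the kept cells of the WT library at day 25 and 7 in those of the KO library, or 0.247 CPM (0.146 to 0.390) and 0.0829 CPM (0.0333 to 0.171). At day 35 the numbers were 8 and 5 UMIs, or 0.259 CPM (0.112 to 0.510) and 0.131 CPM (0.0424 to 0.305). The log2 ratio of KO over WT was -1.57 (-3.07 to -0.24) at day 25 and -0.99 (-2.95 to 0.81) at day 35, so a difference was not detectable at the day 35 depth. Among hair cell-like cells, 7 of 15 cells of the WT library at day 25 (46.7%) held 9 Tmprss3 UMIs, or 45.8 CPM, and none of the 10 cells of the KO library held any, which allows up to 30% of cells to hold a UMI and sets no limit on cells that express the gene. Both day 35 libraries had 1 UMI in this class. Hair cell-like and other otic epithelial-like cells together held 16 UMIs in WT and 1 in KO at day 25 (ratio 0.0819, log2 -3.61, -9.001 to -0.92), and 5 and 2 at day 35 (ratio 0.237, log2 -2.08, -5.47 to 0.53). With stricter limits on genes and mitochondrial share, the day 25 log2 ratio was -0.70 over all cells and -1.93 over other otic epithelial-like cells alone, as no hair cell-like class formed. In all other cells, which were not shown to lack the gene, 0.0209% (WT) and 0.0545% (KO) had a UMI at day 25, and 0.0419% and 0.0547% at day 35. Their median depths were 6139, 6352, 3040 and 4287 UMIs in the same order. Counting from the 3' end can include transcript left outside the deleted part, so the few UMIs of the KO libraries do not test the knockout.

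Otic epithelium made up more of the organoids at day 35 than at day 25 in both genotypes, and its KO over WT share ratio lay below 1 at day 25 and above 1 at day 35. Otic epithelial-like cells other than hair cells were 2.03% of kept cells in WT and 1.48% in KO at day 25 (KO over WT 0.732, 0.592 to 0.904), and 11.6% and 18.0% at day 35 (1.55, 1.42 to 1.69). From day 25 to day 35 their share was 5.73-fold higher in WT (4.91 to 6.71) and 12.1-fold higher in KO (10.3 to 14.3). The class consisted of 2 clusters. Cluster 8 was led by C2cd4b, Rnase1, Clu, Cldn9 and Otoa, the last encoding a tectorial membrane attachment protein, and held 104 WT and 131 KO cells at day 25 and 511 and 733 at day 35. Cluster 15 was led by Otol1, Oc90 and Otog, which encode proteins of the otoconia and other acellular membranes, and held 94 and 35 cells at day 25 and 437 and 475 at day 35. Oc90 itself differed between genotypes, so the sizes of the 2 clusters are not compared. With each library clustered alone the class was 2.02% of WT and 2.32% of KO cells at day 25, the opposite order. At day 35 it was then 5.11% and 11.3%, so the rise between days was smaller in both genotypes.

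Other tissues of the organoids differed in share as well. Keratinocyte-like cells (Krt5, Krt14, Krtdap) were 6.26% of WT and 2.91% of KO cells at day 25 (ratio 0.466) and 1.67% and 2.39% at day 35 (1.44). Neuron-like cells (Tubb3, Stmn2) were 5.59% and 2.67% at day 25 (0.478), and 0.0612% and 0.342% at day 35 (5.58, 2.08 to 18.8). Astrocyte-like cells (Gfap, Aqp4) were 6.14% and 3.28% at day 25 (0.534), whereas at day 35 they were 0.147% of WT and 4.44% of KO cells (30.2, 17.1 to 59.2). Oligodendrocyte lineage-like cells (Mbp, Olig1, Olig2) were 1.72% and 1.23% at day 25 (0.717) and 0.0245% and 0.966% at day 35, where the WT library had only 2 such cells (39.4, 10.5 to 333). Neuron-like cells at day 35 were 1.09% of WT and 0.357% of KO cells, the opposite order, with each library clustered alone. At resolution 2.0 the order of oligodendrocyte lineage-like cells at day 25 turned as well, to 0.594% of WT and 0.652% of KO cells.

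Schwann cell or satellite glia-like cells (Sox10, Gfra3, Foxd3) were 3.21-fold more frequent in KO at day 25 (2.65 to 3.91), and 1.32-fold at day 35 with an interval that included 1 (0.935 to 1.88). Mesenchymal cell or fibroblast-like cells (Dpt, Postn) were 15.4% of WT and 18.0% of KO cells at day 25 (1.17) but 0.527% and 1.38% at day 35 (2.63, 1.81 to 3.86). These day 35 shares depend on the naming of clusters. Unnamed cluster 2, with the fibroblast marker Lum among its leading genes, held 1304 WT and 1219 KO cells at day 35 (1.13, 1.05 to 1.23). Skeletal muscle-like cells (Acta1, Myog) had similar shares at day 25, 9.57% and 10.3%, and at day 35 were 10.5% of WT and 3.88% of KO cells (0.370, 0.321 to 0.426). Cycling cells (Top2a, Cdk1) were 8.35% and 9.96% at day 25 (1.19) and 3.04% and 1.53% at day 35 (0.504). Cells with pluripotency genes (Pou5f1, Dppa5a, Utf1) numbered 12 and 2 at day 25, and 0 in WT against 318 in KO at day 35, or 4.73% (4.23 to 5.26), at least 104-fold higher by the exact lower bound, or 128.6-fold with the WT count at a floor of 3. Immune cell-like cells (C1qa, Tyrobp) numbered 37 in KO at day 25, 1 in KO at day 35 and 0 in both WT libraries. A cluster that comes almost wholly from 1 library, as these last 2 did, may reflect that library and not a cell type of the genotype. When each library was clustered alone, the order turned for skeletal muscle-like cells on both days, to 5.33% of WT and 4.16% of KO cells at day 25 and 5.09% and 7.36% at day 35, and for cycling cells at day 25, to 9.28% and 7.16%. Mesenchymal cell or fibroblast-like cells were then 12.8% of WT and 16.3% of KO cells at day 35, and at resolution 0.5 they were 0.522% and 0.420% at day 25 and 12.5% and 13.4% at day 35. With stricter limits on genes and mitochondrial share, cycling cells were 1.62% and 1.57% at day 35.

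**Figure D1:**
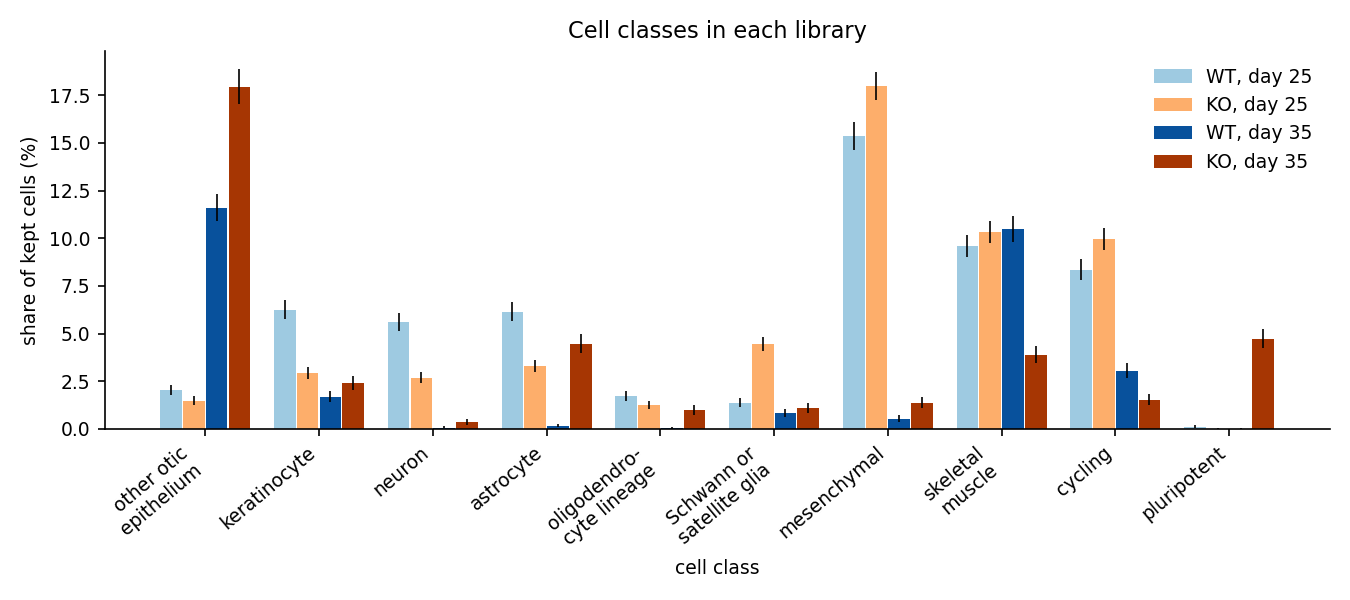
Share of kept cells in each cell class (%, vertical axis) in the WT and KO libraries at day 25 and day 35, with bars for shares and lines for exact 95% binomial intervals that cover counting error alone. Otic epithelial-like cells stand at 11.6% in WT and 18.0% in KO at day 35, and pluripotent-like cells at 4.73% in the KO library at day 35.

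The comparison at the centre of the study is that of hair cells between genotypes. Hair cell-like cells, led by Ccer2, Acbd7, Cabp2, Cd164l2 and Cib3, numbered 15 in WT and 10 in KO at day 25, and 55 and 33 at day 35. They were 0.154% (0.0860 to 0.253) and 0.0894% (0.0429 to 0.164) of kept cells at day 25, and 0.674% (0.508 to 0.876) and 0.490% (0.338 to 0.688) at day 35. The KO over WT ratio was 0.582 (0.234 to 1.38) at day 25 and 0.728 (0.458 to 1.14) at day 35, so neither difference exceeded the counting error. Relative to the other otic epithelial-like cells, hair cell-like cells were less frequent in KO at day 35, with a KO over WT ratio of 0.471 (0.294 to 0.745), while at day 25 the ratio was 0.795 (0.311 to 1.95). Their share was higher at day 35 than at day 25 in both genotypes, 4.39-fold in WT (2.44 to 8.36) and 5.49-fold in KO (2.64 to 12.5). Without the cells of highest doublet score the larger rise was in WT, from 0.0556% to 0.423%. In KO 9 of 10176 cells at day 25 and 18 of 6349 at day 35 were then in the class.

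Hair cell-like cells were rich in mitochondrial RNA, and the limit of 10% on it removed more of them from the WT library at day 35 than from the others. Before the limit, 59.1% of the 137 hair cell-like barcodes of that library exceeded it, against 33.3% of 51 in KO at day 35, and 29.2% and 31.3% at day 25. With no filter on cells the KO over WT ratio of hair cell-like shares at day 35 was 0.487 (0.346 to 0.676). With each library clustered alone, which found 34 cells in WT and 32 in KO at day 35, the ratio was 1.14 (0.682 to 1.91), while the ratio to other otic cells stayed at 0.516 (0.303 to 0.876). At day 25, removing the cells with the highest doublet scores left 5 WT and 9 KO cells, with a ratio of 1.59 (0.479 to 6.04).

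**Figure D2:**
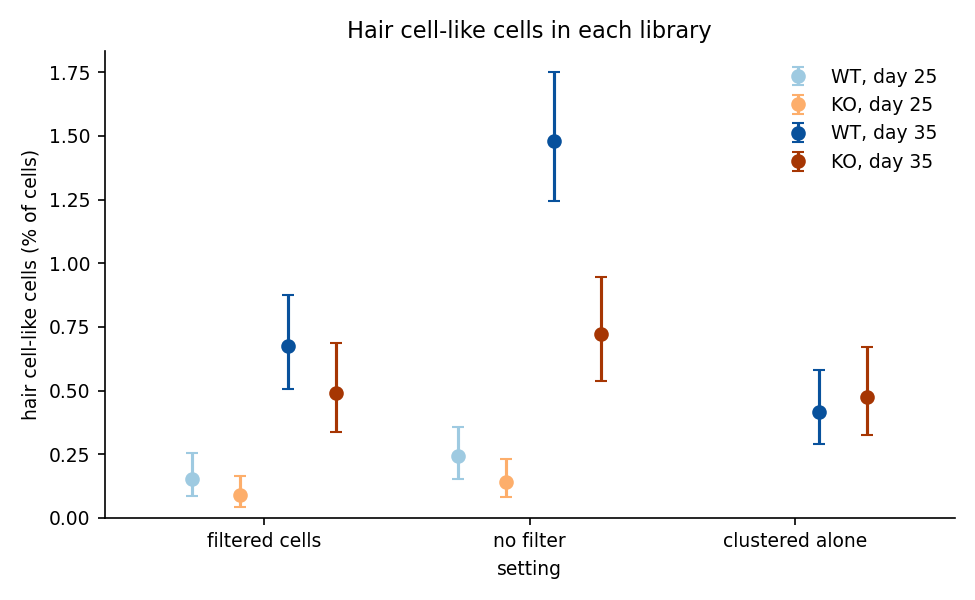
Hair cell-like cells as a share of cells (%, vertical axis) in each library with the cell filter, with no filter, and with each library clustered alone (day 35 only), as points with exact 95% binomial intervals that cover counting error alone. At day 35 the WT share was 0.674% with the filter and 1.48% without, and the KO share 0.490% and 0.721%.

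Within hair cell-like cells, 2 of the genes with at least 50 UMIs on each day met the rule for both days. They differed at least 2-fold in the same direction on both days, with intervals that did not span both directions. At a minimum of 20 UMIs, 9 genes met the rule. H19, a maternally expressed non-coding RNA of the Igf2 locus, was higher in KO, with log2 ratios of 1.22 (0.61 to 1.83) at day 25 and 2.44 (1.71 to 3.24) at day 35. Tmsb10, which encodes the actin monomer-binding protein thymosin beta 10, was lower in KO, with -1.62 (-2.25 to -1.04) and -1.34 (-1.78 to -0.91). Both genes showed the same direction in all 33 pairs of clusters compared across the organoid. The day 25 ratio of H19 was 2.80 with no filter on cells and 3.01 without the cells of highest doublet score. With each library clustered alone, the Tmsb10 ratio in hair cell-like cells at day 35 was -0.0047, and with no filter on cells it was -0.81 at day 25.

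Among the genes ranked for day 25 alone, Cxcl14 (2.099), the transcription factor gene Cebpb (2.25), the actin-severing Gsn (2.05), S100a13 (1.40) and the metallothionein Mt1 (1.29) were higher in KO. Mdk (-2.45), Mia (-3.45), Krt18 (-3.32) and Nnat (-2.39) were lower. Spp1, with 57 UMIs in WT and 0 in KO, was lower, at a log2 ratio of -2.79 with the KO count at a floor of 3 and an exact upper bound of -2.44. Mia was among the leading genes of otic cluster 15, Spp1 of cluster 7, and Apod and Ptgds, given below, of cluster 4. Free RNA of those cells and doublets with them were not separated from expression in hair cell-like cells. With no filter on cells the ratio was 0.11 for Spp1, 2.59 for Mt1 and -4.38 for Mia, and without the cells of highest doublet score it was 2.65 for Gsn, -3.66 for Mdk and -1.60 for Nnat. As means over each cell's own CPM, Cxcl14 had 1.45, Krt18 -2.73 and Mia -2.56. At day 35 alone, Ptgds (2.09), Igfbp2 (1.82) and the cholesterol synthesis genes Fdps (1.41) and Msmo1 (1.38) were higher in KO besides H19. The acute phase genes Saa3 (-4.94, -8.01 to -3.03) and Lcn2 (-4.31, -6.21 to -2.91), the cell cycle inhibitor gene Cdkn1c (-4.07, -5.73 to -2.80), Apod (-2.84) and the calcium buffer gene Pvalb (-2.36, -3.08 to -1.70) were lower. Without the cells of highest doublet score the day 35 ratio was -0.14 for Lcn2, -2.31 for Cdkn1c, 0.54 for Igfbp2 and -1.44 for Ptgds, which thereby turned its direction. Clustering each library alone gave -0.60 for Lcn2, -1.45 for Apod, -1.88 for Cdkn1c, -3.45 for Pvalb and 4.41 for Igfbp2, which had 0.25 at resolution 0.5, and with no filter on cells Msmo1 had 0.74 and Ptgds 0.94.

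Genes of the hair bundle and the mechanotransduction channel had a median log2 ratio of 0.79 (-0.35 to 1.36) at day 25, with 8 of 12 measured members higher in KO (percentile 99.94 among matched random lists). At day 35 their median was -0.02 (-0.54 to 0.39), with 7 of 14 higher, and -0.80 over members with at least 100 UMIs. Espn, which encodes a bundling protein of the stereociliary actin core, had ratios of 0.77 (0.42 to 1.13) and 0.34 (0.08 to 0.60). Cib2, an auxiliary subunit of the transduction channel, had -0.48 (-1.03 to 0.03) and -1.74 (-2.50 to -1.04), and Lhfpl5, another such subunit, -0.35 (-1.10 to 0.35) and -0.80 (-1.42 to -0.22). Of the synapse and ion channel genes, 3 of 3 measured members were higher in KO at day 25 (median 0.85) and 5 of 6 at day 35 (0.32, -0.07 to 1.49), among them Otof, which is needed for exocytosis at the ribbon synapse, at 0.76 (0.11 to 1.39) and 0.20 (-0.44 to 0.83). The day 35 median of this list was -0.36, the opposite sign, with each library clustered alone, and the day 25 median 1.54 without the cells of highest doublet score. The hair cell markers together were at 11920 and 13120 CPM in WT and KO at day 25 and 11850 and 8605 CPM at day 35.

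Cholesterol synthesis genes were higher in the hair cell-like cells of KO at day 35, in 10 of 10 members (median 0.94, 0.42 to 1.41), above all 10000 random lists. At day 25, 5 of 7 members were higher and the interval of the median included 0 (0.85, -0.71 to 2.96). The medians were 2.09 at day 25 and 1.80 at day 35 without the cells of highest doublet score. With no filter on cells the day 35 median was smaller, at 0.41. Msmo1 had ratios of 2.41 (1.43 to 3.45) and 1.38, and Sqle, which encodes squalene epoxidase, 1.10 (-0.56 to 2.69) and 1.58. Hypoxia and glycolysis genes were higher in 19 of 24 members at day 25 (median 0.51, 0.10 to 0.93) and 17 of 24 at day 35 (0.23, -0.0045 to 0.64). Genes of a list of immediate early and dissociation stress genes had a median of -0.45 (-0.71 to 0.65) at day 25, with 9 of 12 lower. At day 35 the median was 0.61 (0.23 to 1.11), with 17 of 18 higher. Examples were Egr1, at -0.72 and 1.11 on the 2 days, and Fosb, at -2.04 and 1.33. The day 35 median of this list was -0.11 without the cells of highest doublet score and 1.27 with each library clustered alone. Extracellular matrix genes were lower in KO at day 25, in 11 of 13 members (median -1.13, -1.79 to -0.13), while at day 35 8 of 15 were higher (median 0.0033, or 0.67 with each library clustered alone). Before filtering, 12 of the 24 hair cell-like barcodes of the WT library at day 25 were among the highest doublet scores, against 1 of 16 in KO, and fibroblast markers reached 2340 CPM in WT and 1287 CPM in KO in the class. Of the imprinted genes 7 of 10 were higher at day 35, and the mitochondrially encoded genes had medians of -0.23 on both days.

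In hair cell-like cells, the rule for genes that differed between days in the same direction in both genotypes named 10 genes higher at day 35, which was its limit, and 9 lower. The stress-induced Nupr1 (log2 day 35 over day 25, 3.26 in WT and 4.67 in KO), Ptgds (3.07 and 4.87), the calcium- and integrin-binding Cib3 (3.16 and 2.77), Calm2, a calmodulin gene (2.26 and 1.08), the chaperone gene Hspa5 (1.69 and 1.21) and Mt2 (2.49 and 1.07) were higher. Gm8797, Defb25, Dpm3 and Vapa were higher as well. Meg3 (-2.15 and -2.79), Actg1 (-1.76 and -1.36), Igfbp2 (-3.48 and -1.47), Gapdh (-1.15 and -1.22), Pcp4 (-1.13 and -1.83), Gm10709, Hnrnpa1 and Prelid1 were among those lower. Hypoxia and glycolysis genes were lower at day 35 in 19 of 25 members in WT (median -0.39) and 19 of 24 in KO (-0.69), and nuclear-encoded oxidative phosphorylation genes were higher in 30 of 36 members in WT (0.57) and 23 of 35 in KO (0.19). Hair bundle genes had a median of -0.05 in WT and -0.68 in KO, where 8 of 10 were lower, but 0.95 in WT without the cells of highest doublet score. With no filter on cells, the Mt2 ratio in KO was -0.41, that of Igfbp2 in KO -0.04 and that of Hspa5 in WT 0.60. Without the cells of highest doublet score the WT ratios were 0.50 for Hspa5, 0.34 for Mt2 and 1.63 for Nupr1, and the KO ratios -0.70 for Pcp4, 0.81 for Dpm3 and 1.53 for Ptgds. Calm2 (3.65) and Cib3 (4.69) in WT, Meg3 in KO (-4.39) and Igfbp2 in both (-4.99 and -3.94) lay farther from 0 under that setting. Gm10709 is a processed pseudogene, whose reads may belong to its parent gene. The day 35 cells of the class were also shallower, at median depths of 2815 (WT) and 4546 (KO) UMIs against 9592 and 6947 at day 25.

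In the other otic epithelial-like cells, taken over clusters 8 and 15, the otoconial gene Oc90 was lower in KO. The otic markers together, Oc90 included, were at 4631 and 2878 CPM in WT and KO at day 25. At day 35 they were at 3637 and 3990 CPM, higher in KO. Oc90 alone gave 3802 of 2371268 UMIs of the class in WT and 292 of 1888881 in KO at day 25. The lower sum in KO at day 25 is therefore not a measure apart from Oc90. Oc90, which encodes the main otoconial matrix protein and marks the class, had log2 ratios of -3.38 (-3.55 to -3.20) at day 25 and -1.96 (-2.29 to -1.63) at day 35, and was lower within each cluster on both days. The urea transporter gene Slc14a1 (-3.15 and -3.24), the heparan sulfate sulfotransferase gene Hs6st2 (-2.33 and -2.13), the transcription factor gene Isl1 (-2.21 and -3.87) and Igf2 (-1.96 and -3.24) were also lower on both days. H19 (2.89, 2.74 to 3.04, and 1.55, 1.40 to 1.71), Itih5 (2.59 and 2.45), Irx3os (2.14 and 2.53), Mest (1.37 and 1.75) and the granin gene Scg2 (1.55 and 1.502) were higher on both days. Irx3os is annotated as antisense, and its reads could not be told from those of an overlapping gene here. Grb10, an imprinted gene, had 86 and 46 UMIs in WT and 0 and 0 in KO, for log2 ratios of -4.51 and -4.73 with the KO counts at a floor of 3 and exact upper bounds of -4.18 and -4.37. The clusters did not share all of these: in cluster 8 at day 25 Slc14a1 had a ratio of 0.05 (-2.17 to 2.38), Hs6st2 0.09 and Isl1 -0.46, Mest had 0.27 (-0.08 to 0.64) in cluster 8 at day 35, and Itih5 had 2.46 and 2.75 in cluster 8 on the 2 days but 0.50 (-1.22 to 2.06) and 0.68 (0.03 to 1.37) in cluster 15. Scg2 had 0.96 in cluster 8 at day 25, and at day 35 0.81 at resolution 2.0 and 7.83 with each library clustered alone, where Slc14a1 had -0.69 at day 25. With stricter limits on genes and mitochondrial share Isl1 had -0.97 at day 25, and Slc14a1 had -1.36, Hs6st2 -1.04 and Oc90 -1.30 at day 35, while H19 had 0.93 at day 35 without the cells of highest doublet score. Values farther from 0 than the main ones included 3.64 for H19 at day 25 at resolution 2.0, -4.26 for Oc90 and -5.58 for Slc14a1 at day 25 and -4.06 for Igf2 at day 35 without the highest doublet scores, and 4.41 for Irx3os and 3.53 for Itih5 at day 35 with each library clustered alone. The median ratio over all measured genes was 0.14 at day 35, and median-ratio scaling moved every day 35 ratio by -0.16 and TMM by -0.10.

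Cholesterol synthesis genes were lower in the KO otic epithelium, the opposite direction to hair cell-like cells of day 35. At day 25, 18 of 19 members were lower (median -0.59, -0.82 to -0.24), and at day 35, 17 of 19 (median -0.62, -0.91 to -0.28), below all 10000 random lists on both days. Fdps, which encodes farnesyl diphosphate synthase, had -1.14 and -1.34, Msmo1 -1.31 and -1.12, Idi1 -0.87 and -1.65, and Hmgcs1, an early enzyme of the pathway, -0.67 and -0.82. The exceptions at day 35 were Mvd (0.03) and Mvk (0.32). Extracellular matrix genes were higher in KO, in 31 of 44 members at day 25 (median 0.55, 0.36 to 0.69) and 35 of 45 at day 35 (0.39, 0.26 to 0.50), above all random lists. Mmp2 (1.28 and 1.04), the elastic fibre gene Fbln5 (1.51 and 0.96), Col11a2 (0.99 and 1.57) and the basement membrane collagen gene Col4a1 (0.63 and 0.52) were higher, whereas the protease inhibitor genes Timp3 (-1.39 and -1.25) and Timp1 (-0.66 and -1.88) were lower. Fibroblast markers in these cells were at 947 CPM in WT and 1573 CPM in KO at day 25, and 888 and 1452 CPM at day 35, against 20810 CPM or more in mesenchymal cell-like cells.

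A fixed list joined genes of membrane serine proteases, the family of Tmprss3, with epithelial sodium channel genes, which are not of that family, and 7 of its 9 measured members were higher in KO on each day, with medians of 0.23 and 0.24 that lay at percentiles 91.88 and 79.2. Tmprss6 had ratios of 1.86 (1.06 to 2.72) and 1.61 (1.10 to 2.15), Tmprss2 1.01 (0.30 to 1.75) and 0.20 (-0.34 to 0.75), and Scnn1b, a sodium channel subunit gene, -1.43 (-2.78 to -0.25) and -0.96 (-1.55 to -0.37). Neighbours of Tmprss3 on chromosome 17 had medians of 0.15 and 0.12. Interferon response genes were higher in 8 of 12 members at day 25 (median 0.49, percentile 99.96) and had a median of 0.05 at day 35. Wnt signalling genes had medians of 0.27 and 0.49, with Wnt5a at 0.79 and 0.80. Notch signalling genes had -0.32 and 0.30, with Hes1 at -0.48 and 0.17 and Hey1 at -0.77 and 0.30. Apoptosis genes had medians of 0.05 and 0.16, p53 response genes -0.03 and 0.03, and genes of the unfolded protein response -0.05 and -0.07.

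**Figure D3:**
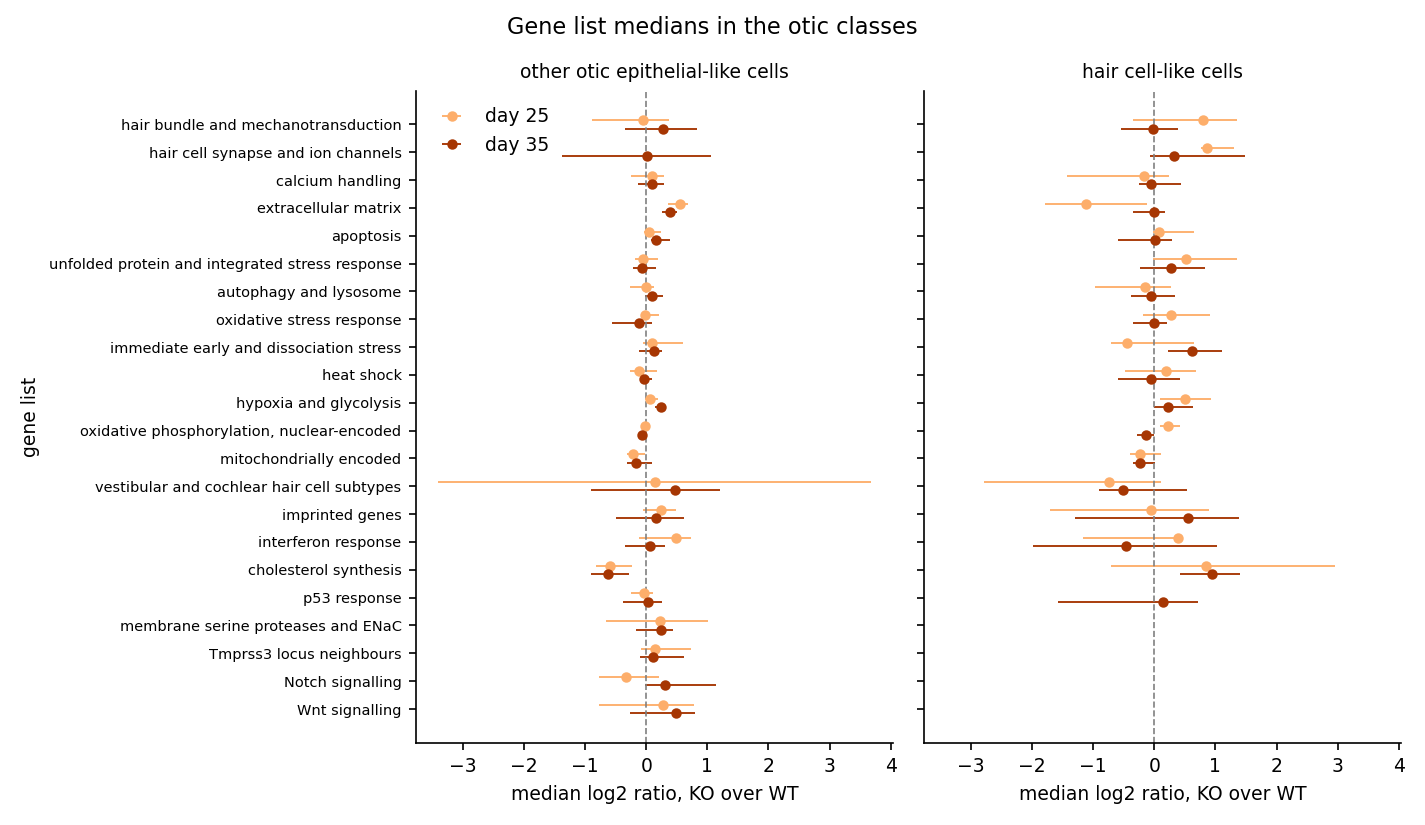
Median log2 ratio of CPM, KO over WT (horizontal axis), of the measured members of each gene list in other otic epithelial-like cells (left) and hair cell-like cells (right), with day 25 and day 35 as separate points and lines for the order-statistic 95% interval of the median over members. Cholesterol synthesis lies at -0.59 and -0.62 in the otic class and at 0.85 and 0.94 in hair cell-like cells.

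A few genes differed in the same direction in every pair of clusters in which they were measured. Over 33 pairs of clusters, 19 at day 25 and 14 at day 35, 7003 genes were measured in at least 50% of the pairs, and 5 of them had the same direction in every pair and at least a 2-fold difference in 50% or more. H19 (chromosome 7, 142575529 to 142578143) was higher in KO in 33 of 33 pairs (median log2 2.13), while Igf2, its paternally expressed neighbour (chromosome 7, 142650766 to 142666816), was lower in 32 of 32 (-2.97). Cdkn1c (chromosome 7) was lower in 30 of 30 (-3.33), and Igf2r (chromosome 17), the receptor that clears Igf2, in 23 of 23 (-1.53). These 4 genes are imprinted, expressed from the allele of 1 parent. The remaining gene, Gm7334, was higher in 22 of 22 pairs (1.38), but it is a processed pseudogene whose reads may be shared with its parent gene. The hair cell-like cluster was too small to be among the pairs, and there Cdkn1c had a log2 ratio of -0.10 (-0.98 to 0.72) at day 25. The pairs within a day share 2 libraries and their free RNA, so they are not independent measurements.

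Other imprinted genes differed as well. Peg3 (31 of 31, median 0.81), Snrpn (31 of 31, 0.83), Mest (30 of 31, 0.90), Ndn (29 of 29, 0.48), Usp29 (12 of 12, 0.66) and Zrsr1 (15 of 15, 0.40) were higher in KO, and Grb10 (12 of 13, -5.21), Zim1 (7 of 7, -4.95) and Dlk1 (28 of 31, -0.62) were lower. Nnat (-0.08), Peg10 (-0.07), Impact (-0.02), Plagl1 (-0.01) and Kcnq1ot1 (0.04) had medians near 0. In the otic class the median size of the imprinted list's log2 ratios was 0.50 at day 25 (percentile 99.98) and 0.60 at day 35 (percentile 100). Outside the list, Tmsb10 was lower in 33 of 33 pairs (-0.96), Tgoln1 in 27 of 27 (-0.80), Reg3g in 10 of 10 (-2.48) and Lcn2 in 29 of 31 (-1.04).

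**Figure D4:**
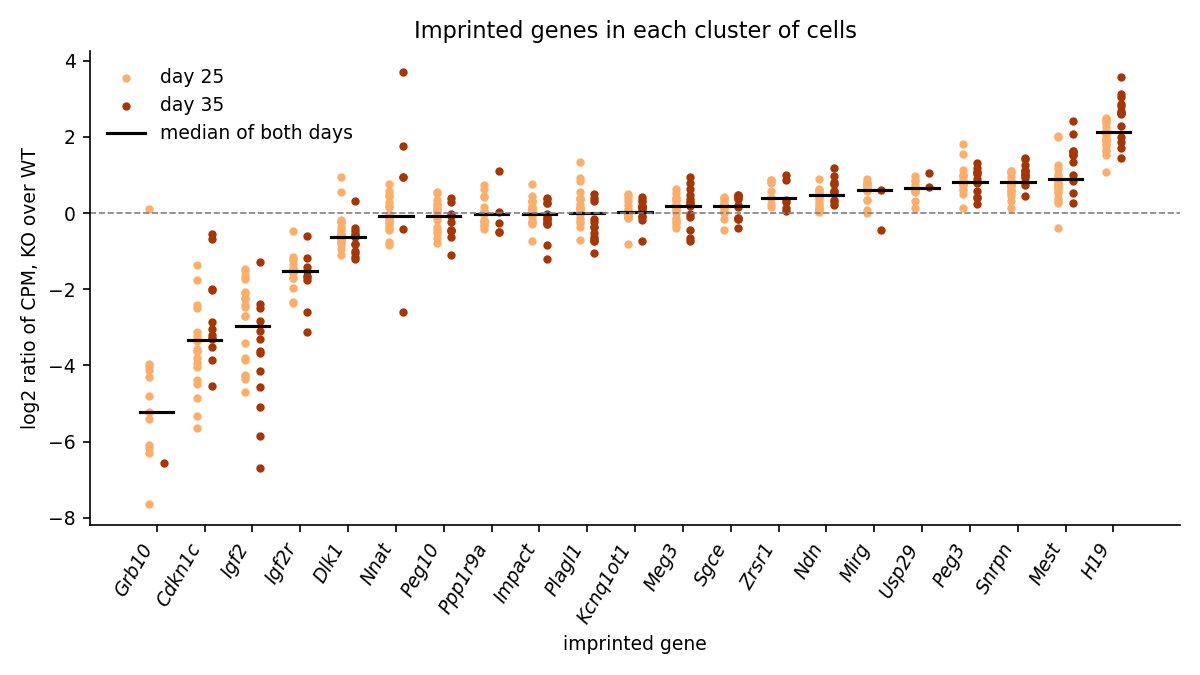
Log2 ratio of CPM, KO over WT (vertical axis), of each imprinted gene measured in at least 10 pairs of clusters, with 1 point per cluster and day and a line at the median of both days. H19 lies above 0 in all 33 points, and Igf2, Cdkn1c and Igf2r below 0 in all of theirs.

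Differences in 3 further classes with at least 50 cells in every library followed the same rule of size. In skeletal muscle-like cells H19 (2.20 and 2.59), Cck (1.77 and 2.53), Mest (1.12 and 1.36), Gm7334 (1.37 and 1.48) and Blcap (1.18 and 1.36) were higher in KO on both days. Igf2 (-3.92 and -4.28), Cdkn1c (-4.00 and -3.48), Zim1 (-3.36 and -5.15), the slow muscle light chain gene Myl3 (-2.71 and -3.25) and Igf2r (-1.69 and -2.55) were lower. Keratinocyte-like cells of KO had more H19 (1.58 and 2.29), the protease inhibitor gene Cst6 (2.84 and 1.52), Ltf (2.26 and 1.67), the heat shock gene Hspa1a (1.24 and 2.099) and Ly6g6c (1.69 and 1.30), and less Igf2 (-2.39 and -7.13), the antimicrobial lectin gene Reg3g (-1.90 and -5.09), Tmsb10 (-1.32 and -1.57), Tm4sf1 and Tgoln1. In Schwann cell or satellite glia-like cells H19 (2.08 and 2.67) and Sostdc1 (1.53 and 1.97) were higher and Spp1 (-1.48 and -1.84) was lower. Extracellular matrix genes were higher at day 25 in muscle-like cells (39 of 45, median 0.43) and Schwann cell-like cells (35 of 42, 0.52) of KO, with 26 of 46 (0.073) in keratinocyte-like cells. Cholesterol synthesis genes were lower at day 35 in muscle-like and Schwann cell-like cells, in 16 of 19 (-0.30) and 7 of 7 (-0.94), but higher in keratinocyte-like cells, in 17 of 19 (0.77).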

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

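The tests of doublets, of dilution, of the mitochondrial limit and of lost methylation at every imprinting control region were chosen only after the results were seen; those of copy number, imprinting state and shared barcodes were written before.

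H19, Igf2, Cdkn1c and Igf2r differed between genotypes in every measured pair of clusters. A gain or loss of a chromosome in most cells was argued against by the chromosome medians in the otic class, by a rule that used the lower of the 2 days. The median farthest from 0 was that of chromosome 11 on both days, at 0.0871 at day 25 and 0.235 (0.212 to 0.255) at day 35. The day 35 value lay 0.096 above the median of all genes. A gain in a part of the cells was not excluded. A different imprinting state of the lines is a candidate explanation, since the imprinted list's ratios were larger in size than those of at least 99.98% of matched random lists on both days, or of 98.7% and 99.98% without the genes shared by all clusters. By the rule used, 7 of 20 genes argued against loss of methylation at every imprinting control region in KO, with none of it in WT. These (Impact, Kcnq1ot1, Meg3, Nnat, Peg10, Plagl1 and Sgce) had medians whose intervals lay under 0.5 in the direction such a loss gives. The rule cannot decide the question, because the intervals treat pairs of clusters as independent and genes were counted, not control regions. Of the 20 genes, 16 went in that direction in most of their pairs and 9 in every pair. Dlk1 (28 of 31 pairs, 0.62 in that direction), Mirg (13 of 15, 0.62) and Cdkn1c (30 of 30, 3.33) were among the 16. Ratios of KO over WT cannot show a loss that both lines share, so loss at every region in KO was not excluded. Loss at some regions stays open, no methylation data were analysed here, and with 1 line per genotype an effect of Tmprss3 cannot be separated from a difference between the lines.

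The 318 pluripotent-like cells of the KO library at day 35 were 4.73% of its cells. Of their barcodes 17 of 318, 5.35% (3.15 to 8.42), occurred in another library. This missed the bound of under 5% that was written before for ruling out index hopping. That bound lay close to the 3.82% of all barcodes of that library that were shared. The interval lay far below a majority of the barcodes, which argues against hopping as their main source, by a limit applied in place of that bound. Of the 14 pluripotent-like barcodes of the other libraries, 0 were pluripotent-like in that library (upper bound 23.2%). Doublets were left open, because the doublet caller had not worked: 15 of 318, 4.72% (2.66 to 7.66), were among the highest scores, which were taken at a rate of 5.66%. The pluripotent-like cells had a median depth of 14026 UMIs, against 4420 over all kept cells of that library. Stem cells that did not differentiate may account for them, which 1 library cannot test, and their free RNA may reach other classes, as pluripotency markers were at 49.2 CPM in the KO otic class at day 35 and 1.09 CPM in WT.

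The share of hair cell-like cells had KO over WT ratios of 0.582 and 0.728 with intervals that included 1, and of 0.487 (0.346 to 0.676) at day 35 without any filter. Removal by the mitochondrial limit was excluded as the cause of the lower KO share at day 35, since it removed 33.3% (20.8 to 47.9) of the KO and 59.1% (50.4 to 67.4) of the WT hair cell-like barcodes. Dilution by tissue other than otic epithelium was argued against in the day 35 libraries. There other otic cells were more frequent in KO (1.55, 1.42 to 1.69) and the ratio of hair cell-like to these cells was 0.471 (0.294 to 0.745). These intervals do not cover variation between cultures, so dilution was not excluded. At day 25 such dilution and a lower yield or survival of hair cells in KO cannot be told apart, as the ratio to other otic cells was 0.795 (0.311 to 1.95), on 15 and 10 cells. At day 35 a lower yield or survival and a larger otic epithelium around the hair cells stay open with 1 library per genotype, and with each library clustered alone the share ratio was 1.14 (0.682 to 1.91).

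Some share ratios of KO over WT lay on opposite sides of 1 on the 2 days, and these differences between days were not tested. They were 0.732 and 1.55 for other otic epithelial-like cells, 0.466 and 1.44 for keratinocyte-like, 0.478 and 5.58 for neuron-like, 0.534 and 30.2 for astrocyte-like, 0.717 and 39.4 for oligodendrocyte lineage-like, 1.19 and 0.504 for cycling, and 0.146 and 128.6 (with the WT count at a floor of 3, lower bound 104) for pluripotent-like cells. With each library clustered alone, the order of WT and KO turned for neuron-like cells at day 35 (1.09% and 0.357%) and for other otic epithelial-like (2.02% and 2.32%) and cycling cells (9.28% and 7.16%) at day 25, and at resolution 2.0 for oligodendrocyte lineage-like cells at day 25 (0.594% and 0.652%). Within hair cell-like cells, log2 ratios of opposite sign at day 25 and day 35, also untested, were 2.92 and -4.31 for Lcn2, -3.45 and 0.72 for Mia, 1.29 and -0.41 for Mt1, -2.39 and 3.46 for Nnat, and 1.40 and -0.65 for S100a13. The day 25 value of Lcn2 rested on 4 UMIs in WT and 11 in KO and the day 35 value of Nnat on 1 and 9 (0.61 to 8.92), under the minimum of 50.

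Gene lists had medians of opposite sign on the 2 days, again untested. Immediate early genes had -0.45 and 0.61 in hair cell-like, 0.16 and -0.89 in keratinocyte-like and 0.37 and -0.24 in Schwann cell-like cells. In hair cell-like cells the day 25 interval spanned both signs. The day 35 median there was -0.11, the sign of day 25, without the cells of highest doublet score. Keratinocyte-like cells had -0.39 and 0.37 for hypoxia and glycolysis genes and -0.18 and 0.77 for cholesterol synthesis genes. Between hair cell-like and other otic cells of the same day, untested differences in sign were -1.13 and 0.55 for extracellular matrix genes at day 25, 0.85 (-0.71 to 2.96) and -0.59 (day 25) and 0.94 and -0.62 (day 35) for cholesterol synthesis genes, and -0.51 and 0.47 for vestibular and cochlear hair cell subtype genes at day 35.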

How the results depend on the processing

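Removal of the top doublet scores and use of each otic cluster alone were chosen only after the results were seen. The labels give no replicate numbers that pair libraries, and no model with day as a block was fitted. Of the values under alternatives, 2485 of the secondary results were the same, 271 moved beyond their intervals and 9 reversed. Of the main results 225 were the same and 45 moved. Only a result whose main interval did not span both directions could count as reversed. The hair cell-like log2 share ratios of both days, which changed sign under an alternative, therefore counted as moved. The cause of these moves was not tested. Without top doublet scores, hair cell-like shares were 0.0556% (WT, day 25), 0.423% (WT, day 35) and 0.284% (KO, day 35), the log2 share ratio at day 25 was 0.67, and the KO otic share at day 35 was 17.0%. Ptgds in hair cell-like cells (day 35) was -1.44, and immediate early genes were -0.11 for KO over WT at day 35 and -0.15 for day 35 over day 25 in KO. H19 was 3.01 in hair cell-like cells at day 25 and 0.93 in otic cells at day 35, Igf2 in otic cells at day 35 -4.06, and cholesterol synthesis in hair cell-like cells at day 35 1.80. With no filter on cells, hair cell-like shares at day 35 were 1.48% and 0.721% and the WT otic share 12.9%. H19 was 2.80, Tmsb10 -0.81 and Spp1 0.11 in hair cell-like cells at day 25, cholesterol synthesis 0.41 at day 35, and Mt2 (day 35 over day 25, KO) -0.41. With at least 1000 genes and at most 5% mitochondrial UMIs no hair cell-like class formed. Otic shares were then 1.69% (WT, day 25), 9.18% (WT, day 35) and 12.0% (KO, day 35), the pluripotent-like share 5.45%, H19 in otic cells 2.72 and 1.75, and mitochondrially encoded genes in otic cells at day 25 0.078. At resolution 2.0 otic shares were 1.43%, 1.26%, 7.19% and 14.7% and H19 in otic cells 3.64 and 1.38. With each library clustered alone no hair cell-like class formed at day 25. The WT hair cell-like share at day 35 was 0.416%, the log2 share ratio 0.19 and Tmsb10 -0.0047. Otic shares were 2.32% (KO, day 25), 5.11% (WT, day 35) and 11.3% (KO, day 35), and otic values at day 35 were 1.27 for H19, 0.76 for extracellular matrix and -0.93 for cholesterol synthesis. In cluster 8 alone at day 25, H19 was 2.48, Hs6st2 0.092, Slc14a1 0.051, extracellular matrix 0.74 and mitochondrially encoded genes 0.070, and Igf2 at day 35 was -3.68. In cluster 15 alone, H19 was 3.24, Igf2 -3.42 and extracellular matrix 0.175 at day 25, and extracellular matrix 0.55 at day 35. Median-ratio scaling gave 1.39 for H19 and 0.23 for extracellular matrix in otic cells at day 35. It shifted all hair cell-like ratios by -0.15 at day 25 and -0.11 at day 35, and TMM shifted those of day 25 by -0.19. A minimum of 20, 50 or 200 UMIs named 9, 2 or 1 genes for both days in hair cell-like cells. Keeping doublets was the main setting itself, and thinning left too few Tmprss3 UMIs for a ratio. Of the 5 classes compared gene by gene, the lowest UMI total was that of hair cell-like cells of KO at day 25, with 71473.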

Other observations

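The results below were described after the data were seen, and none was tested. Several clusters that matched no marker set differed in share between genotypes. Cluster 12, led by Gm6619, Cldn10, Lect1 and Napsa, had KO over WT ratios of 0.288 (0.223 to 0.368) at day 25 and 0.499 (0.433 to 0.575) at day 35. Cluster 19, led by Coch and Crabp1, had 0.443 and 0.347. Cluster 0, led by Ibsp and Pgf, had 1.48 and 2.28, and cluster 11, led by Otor and Cldn11, had 0.887 and 4.71. Cluster 21, led by the adipocyte genes Retn and Adipoq, had 0.913 (0.713 to 1.17) and 8.34 (4.92 to 15.1). Cluster 18, led by Chodl, C1qtnf3 and the myogenic factor gene Myf5, had 0.385 (0.319 to 0.463) at day 35. At the same day cluster 3, led by Fgf21 and Hspa5, had 0.644 (0.590 to 0.703), and cluster 4, led by Otos and Apod, had 0.693 (0.634 to 0.757).

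Other otic epithelial-like cells differed between days in both genotypes. Extracellular matrix genes were lower at day 35 in 37 of 43 members in WT (median -0.60) and 41 of 45 in KO (-0.80), and the WT median was -1.28 without the highest doublet scores. Immediate early and dissociation stress genes were higher in 18 of 20 members in each genotype (0.59 and 0.60), and heat shock genes in 13 and 12 of 15 (0.62 and 0.75). Before filtering, the median mitochondrial share of the class was 3.65% in WT and 3.62% in KO at day 25, and 6.81% and 5.36% at day 35. Median UMIs were 7729 and 8017 at day 25, and 3609 and 5207 at day 35. Stress of the tissue and of its dissociation were not told apart. Notch signalling genes had medians of -1.20 in WT and -0.25 in KO, and interferon response genes 0.79 and 0.11.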
